A study of Mus musculus with 23 samples.

How the data were processed

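RNA sequencing libraries were made with a stranded mRNA kit (TruSeq) from RNA extracted on RNeasy columns and checked on a TapeStation, per the labels' protocols. Macrophages were sorted from subcutaneous tumours as cells with CD45, CD11b and high F4/80 and without Gr1, tumour cells came from culture, and colonies were taken after 9 days in a haematopoietic stem cell medium, per the labels. The values are expected counts per gene (estimated read counts that need not be whole), which the authors deposited as 2 tables, of 20 libraries and of the 3 HPV-negative colony libraries, and the column headers are those of RSEM, a program that divides reads among the transcripts they fit. The submitters' processing notes name STAR 2.5.3a, RSEM 1.3.0, FastQC and MultiQC on the mouse build mm10/GRCm38. The role and order of these tools, the strand setting, the annotation release and any filter on reads are not given in the sources used here. Both tables hold unscaled counts, so libraries of both entered the same fits, and any difference in handling between the tables goes along with the HPV-negative colony group.

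The tables hold 36793 genes as Ensembl identifiers, of which 35243 (95.8%) matched a symbol of the GENCODE M21 annotation, whose GRCm38 coordinates are given, 1-based. No column belonged to a sample outside the series. Of all values 13.1% were not whole, and counts were rounded for the tests, which moved no value by more than 0.5 counts. RSEM splits reads that fit several genes, so genes with near-identical copies and pseudogenes are uncertain, and with no stated strand setting the same holds for overlapping and antisense genes.

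Libraries were grouped by the labels alone. Each comparison was tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3), with TMM normalisation, filterByExpr (minimum count 10, minimum total 15), a prior count of 0.125 for fold changes and Benjamini-Hochberg adjustment at 0.05. The 9 macrophage libraries shared a fit, as did the 9 tumour-cell libraries, the 11 colony and macrophage libraries of HPV-negative MEER and SCCVII, and the 18 macrophage and tumour-cell libraries. The interaction asks whether the change from macrophage to colony differs between SCCVII and HPV-negative MEER. Gene groups were 36 lists of pathways and cell types, tested against all other genes with camera in limma 3.58.1 at a preset correlation of 0.01 and again with the correlation estimated from the data, and adjusted over the lists of a comparison. Of the lists tested in each comparison, the calls went from 13 to 1, from 19 to 1 and from 17 to 1 with an estimated correlation in the macrophage comparisons, in the order of the report, and from 11 to 0, 8 to 1 and 8 to 1 in the comparisons of lines. They went from 14 to 4, 22 to 5 and 15 to 1 for macrophages against lines of HPV-negative MEER, HPV-positive MEER and SCCVII, and to 0 in each colony comparison and in the interaction. The lists, tests, groups, alternatives and the rule for naming genes were chosen before the data were examined, except where the text says otherwise.

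Levels are CPM scaled by TMM over the 23 libraries (17014 genes kept). In comparisons between groups, where every library of a group had 0 counts, a fold is given as a bound against 3 counts summed over that group's libraries, and where a group held 1 to 3 counts the levels are given and no fold. The interaction gives fitted sizes for such genes, which depend on the prior count. Depth was 26848759 to 47609481 counts, and 12803 to 15560 genes per library had at least 10 counts. The biological coefficient of variation was 16% in the fit of macrophages, 18.1% in that of lines, 40.2% in that of colonies with macrophages and 17.6% in that of macrophages with lines. Every pair of replicates differed by more than sampling noise, with a chi-square per gene of at least 3.23, so no library was counted as a repeat of another.

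Genes were named by rule. From each comparison the rule takes the 10 largest rises and falls (5 in the comparisons against HPV-positive MEER, of macrophages with lines and between colonies) among called genes whose groups do not overlap, with at least 10 CPM in every library of the higher group and leaving out predicted and unnamed genes. It adds up to 2 members with the largest rise and 2 with the largest fall of each list used, a fixed set of macrophage and tumour genes given whatever their test, strain and sex markers, and the 3 largest changes each way of the interaction. The text leaves out some of these for length, and 1 is not reported here.

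The fit was tested on simulated counts drawn from the real means and library sizes with 200 genes changed. All genes and libraries of a fit were given the same spread. For HPV-positive against HPV-negative macrophages (13996 genes), 16, 47, 50 and 50 of 50 genes changed 1.5, 2, 4 and 8-fold were called, with 13 false calls. For the same comparison of lines (14163 genes) these were 8, 41, 50 and 50 of 50, with 6 false calls. For SCCVII colonies against macrophages (15718 genes) they were 0, 1, 18 and 47 of 50, with 3 false calls, so changes of up to 4-fold were mostly missed there. In the real data the chi-square per gene was 273 between SCCVII colonies and at most 11.5 between SCCVII macrophages. The simulated colony figures, drawn with equal spread, need not hold for these data. Alternatives were size factors of the RLE kind, no filter, the Wald test of DESeq2 1.42.0, the compared groups alone, all 23 libraries, the replicate number as a block, an estimated correlation between genes, and leaving out each library in turn. The replicate block kept only those libraries of the compared groups that have a same-numbered partner. In the colony comparisons and the interaction few libraries were then left to estimate the spread. HPV-positive colonies and the SCCVII colony numbered 3 were not analysed here.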

Results

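RNA sequencing measured gene transcripts in 3 kinds of mouse sample: macrophages sorted from implanted head and neck tumours, the tumour cells grown in culture, and colonies that the labels describe as derived from such macrophages. MEER cells are mouse oropharyngeal epithelial cells transformed with an activated Ras, used in a form that carries papillomavirus oncogenes (HPV-positive) and a form without them (HPV-negative), in the C57/Bl6 strain. SCCVII is a squamous carcinoma line of the C3H/HeJ strain. Macrophages carried CD45, CD11b and high F4/80 and lacked Gr1, and each macrophage library pooled cells of 3 to 4 mice. Each group had 3 libraries, except SCCVII colonies with 2, which makes 23 libraries in 8 groups. The tumour-cell libraries are aliquots of cultured lines, so their p-values measure only the spread between these samples, which may be technical. Colonies, described by the labels as macrophage progenitors, had been kept for 9 days in a medium for haematopoietic stem cells.

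Depth ran from 26848759 to 47609481 expected counts per library, so 1 CPM, the unit of all levels here, stood for 26.8 to 47.6 counts. By group the totals were 33237978 to 35605463 in HPV-negative macrophages, 26848759 to 31680904 in HPV-positive macrophages and 31061554 to 32674678 in SCCVII macrophages. They were 27944725 to 36324706, 28002705 to 36024739 and 27596445 to 34938060 in the HPV-negative, HPV-positive and SCCVII lines, and 29311677 to 47609481 and 28136747 to 31993125 in HPV-negative and SCCVII colonies. The floor of 3 counts in a library lay between 0.063 and 0.112 CPM. Floors cover counting error only, and the reads carry no molecular identifiers. The SDs and SEs given below also hold the spread between libraries. The first principal component of log expression held 52.1% of the variance and separated macrophages from lines, and the second, with 16.4%, separated SCCVII from MEER samples. Levels are mean CPM ± SD over the 3 libraries of a group (2 for SCCVII colonies), and log2 changes carry their standard error (SE).

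The comparison of macrophages from HPV-positive with those from HPV-negative MEER tumours asks whether the viral status of a tumour goes with the state of its macrophages. Each status is a single MEER line, so the virus cannot be told apart from other differences between the lines. The p-values cover the spread between macrophage pools. Inflammatory and checkpoint genes were higher in macrophages of HPV-positive tumours. Nos2, the inducible nitric oxide synthase (GRCm38 chromosome 11, 78920787 to 78960254), stood at 410 ± 32.5 CPM against 38.6 ± 0.714, a log2 change of 3.43 ± 0.09 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 4.6e-08). Cd274, which encodes the checkpoint ligand PD-L1 (chromosome 19, 29367455 to 29388095), stood at 679 ± 41.2 against 92.7 ± 17 CPM, a log2 change of 2.9 ± 0.13 (adjusted p = 7.3e-07). Pdcd1lg2, the other ligand of the same receptor, rose by a log2 of 5.66 ± 0.39, from 3.65 ± 2.08 to 180 ± 24 CPM. The chemokine genes Ccl24 and Ccl17 were among the largest rises, with Ccl24, which attracts eosinophils, at 1675 ± 371 against 9.59 ± 1.79 CPM and Ccl17, which attracts T cells (chromosome 8, 94810453 to 94812036) at 66.1 ± 33.6 against 1.24 ± 0.19 CPM.

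Among the fixed gene lists, all 21 measured classical inflammatory genes rose, and 21 rose when adjusted over the list alone (camera adjusted p = 8.1e-24 with a preset correlation of 0.01, adjusted p = 0.12 with an estimated correlation). Il1a rose by 4.36 ± 0.3 and Ptgs2, the inducible prostaglandin synthase, by 3.94 ± 0.14 on the log2 scale. Of 17 alternative activation genes 15 rose and none fell over all genes, and 16 rose when adjusted over the list alone (camera adjusted p = 2.6e-18, adjusted p = 0.044 with an estimated correlation). Arg1, the arginase of that programme (chromosome 10, 24915221 to 24927484), did not pass the test, at 1785 ± 474 against 1629 ± 239 CPM (log2 0.16 ± 0.18, adjusted p = 0.49). Of 22 hypoxia and glycolysis genes 20 rose and none fell (the same counts adjusted over the list alone, camera adjusted p = 4.8e-18, adjusted p = 0.2 with an estimated correlation). Vegfa, the angiogenic growth factor, was at 820 ± 14.8 against 144 ± 10.3 CPM, a log2 change of 2.53 ± 0.08. All 12 MHC class II genes rose (12 adjusted over the list alone, camera adjusted p = 2.5e-06, adjusted p = 0.38 with an estimated correlation). Of 15 MHC class I genes 11 rose and none fell (11 adjusted over the list alone, camera adjusted p = 0.012, adjusted p = 0.82 with an estimated correlation), and that list's adjusted p was 0.075 without HPV-negative macrophage library 4. Of 17 checkpoint genes 12 rose and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 4.7e-05, adjusted p = 0.25 with an estimated correlation).

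Markers of other leucocytes moved with these groups. Of 13 dendritic cell genes 10 rose (11 adjusted over the list alone, camera adjusted p = 6.2e-05, adjusted p = 0.41 with an estimated correlation). The migration receptor Ccr7 stood at 99.5 ± 54.8 against 5.47 CPM. Of 4 eosinophil genes 3 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.003, adjusted p = 0.25 with an estimated correlation), among them Siglecf, which rose by 5.38 ± 0.28. Of 14 T cell genes 1 rose and none fell, and 0 rose when adjusted over the list alone (edgeR calls, camera adjusted p = 0.71).

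Genes of division and of resident-type macrophages were lower in the HPV-positive setting. All 22 mitotic genes fell (22 adjusted over the list alone, camera adjusted p = 2.5e-18, adjusted p = 0.2 with an estimated correlation). The cyclin Ccnb1 stood at 15.3 against 44.3 CPM and the proliferation marker Mki67 at 138 ± 12.7 against 248 ± 40.2 CPM (log2 -0.83 ± 0.12, adjusted p = 0.00054). Of 28 E2F and DNA replication genes 23 fell and 1 rose (24 and 1 adjusted over the list alone, camera adjusted p = 8.4e-08, adjusted p = 0.2 with an estimated correlation). Of 18 resident-type macrophage genes 11 fell and 1 rose (11 and 1 adjusted over the list alone, camera adjusted p = 0.00036, adjusted p = 0.71 with an estimated correlation), among them Mrc1, the mannose receptor, at 938 ± 189 against 2067 ± 582 CPM (log2 -1.11 ± 0.21). Cx3cr1, the fractalkine receptor, changed by -1.73 ± 0.21, from 946 to 280 CPM. Ctsk, the collagen-degrading cathepsin K (chromosome 3, 95499256 to 95509362), was among the largest falls, at 3.3 ± 1.74 against 358 ± 109 CPM. Csf1r, the receptor that macrophages need to survive, did not pass the test (log2 -0.05 ± 0.11, adjusted p = 0.75), and of 17 macrophage identity genes 6 rose and 6 fell (the same counts adjusted over the list alone, camera adjusted p = 0.71). In all, 3206 genes were higher and 3647 lower of 14085 tested, 6853 in total, against 3708 with all 23 libraries in the fit (1573 higher and 2135 lower). HPV-negative macrophage library 4 held the epithelial keratin Krt8 at 59 CPM, against 20.8 and 13.4 CPM in libraries 1 and 2, and the collagen Col1a1 at 30.2 CPM, against 4.79 and 4.3 CPM (both genes chosen after their values were seen). Transcripts of the HPV-negative line stood in it at a median of 5.51% of their level in the line, against 0.557% and 0.624%, and those of both MEER lines at 12.6%, against 1.96% and 1.45%. The set of both MEER lines was chosen as low in SCCVII samples and not as low in MEER macrophages. It holds genes such as Rpl3 and Rps3a1, so it does not mark tumour cells alone.

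**Figure D1:**
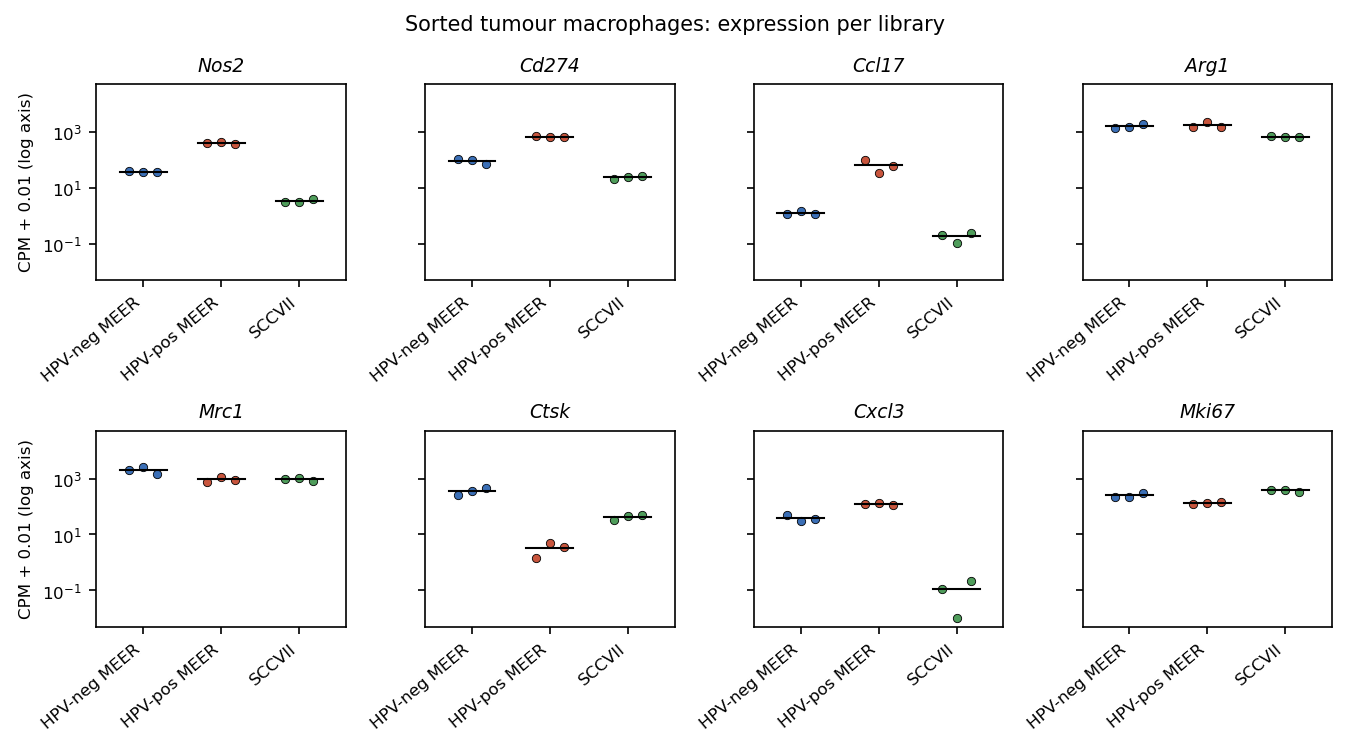
Expression of 8 genes in macrophages sorted from HPV-negative MEER, HPV-positive MEER and SCCVII tumours, as CPM + 0.01 on a log axis, where each point is a library and each black line the group mean. Nos2 averaged 38.6, 410 and 3.42 CPM in the 3 groups in that order, and Cd274 averaged 92.7, 679 and 24 CPM.

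SCCVII macrophages were compared with HPV-negative MEER macrophages to set a second HPV-negative tumour beside the first, with model and mouse strain changing together and, by Xist, perhaps the sex of the hosts. Inflammatory genes were lower in SCCVII macrophages. Nos2 stood at 3.42 ± 0.443 against 38.6 CPM (log2 -3.52 ± 0.1, edgeR quasi-likelihood adjusted p = 1.6e-08), Cd274 at 24 ± 2.18 against 92.7 CPM (log2 -1.97 ± 0.13, adjusted p = 5.1e-06) and Arg1 at 680 ± 36.6 against 1629 CPM (log2 -1.28 ± 0.18, adjusted p = 0.00048). Cxcl3, a neutrophil chemokine (chromosome 5, 90786103 to 90789600), changed by -8.52 ± 0.38 from 38.2 ± 9.68 to 0.102 CPM. Thbs1, the matrix protein thrombospondin, was at 4.17 against 946 ± 131 CPM and Spint1, an epithelial protease inhibitor, at 0.337 against 257 ± 96.2 CPM. Apoe, the lipid carrier, changed by -5.47 ± 0.33, from 9263 ± 3859 to 211 CPM.

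Of 24 myeloid-acting cytokine genes 18 fell and none rose (18 adjusted over the list alone), a shift that held with an estimated correlation (camera adjusted p = 7e-11 preset and adjusted p = 0.009 estimated). Of 21 classical inflammatory genes 18 fell and none rose (18 adjusted over the list alone, camera adjusted p = 3.4e-17, adjusted p = 0.18 with an estimated correlation). Of 17 alternative activation genes 16 fell and 1 rose (16 and 1 adjusted over the list alone, camera adjusted p = 3.7e-08, adjusted p = 0.16 with an estimated correlation). Of 12 MHC class II genes 10 fell (10 adjusted over the list alone, camera adjusted p = 0.0019, adjusted p = 0.57 with an estimated correlation). H2-Ab1 stood at 152 against 2015 ± 1019 CPM. Of 10 osteoclast genes 9 fell (9 adjusted over the list alone, camera adjusted p = 1.5e-08, adjusted p = 0.1 with an estimated correlation), among them Mmp9, a gelatinase, at 17.8 against 582 ± 203 CPM. All 6 neutrophil genes fell (6 adjusted over the list alone, camera adjusted p = 0.0027, adjusted p = 0.16 with an estimated correlation), as did 8 of 11 natural killer cell genes (9 adjusted over the list alone, camera adjusted p = 0.0019, adjusted p = 0.48 with an estimated correlation).

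Division genes were higher in SCCVII macrophages. Of 22 mitotic genes 19 rose and none fell (21 adjusted over the list alone, camera adjusted p = 6e-06, adjusted p = 0.5 with an estimated correlation), and of 28 E2F genes 22 rose and 1 fell (23 and 1 adjusted over the list alone, camera adjusted p = 2.6e-05, adjusted p = 0.39 with an estimated correlation). Mki67 stood at 374 ± 31.9 against 248 CPM (log2 0.57 ± 0.12). Of 28 interferon-stimulated genes 10 rose and 4 fell (10 and 4 adjusted over the list alone, camera adjusted p = 0.014, adjusted p = 0.74 with an estimated correlation), and without HPV-negative macrophage library 4 that list's adjusted p was 0.21. Ifi44l, an interferon-induced gene, was at 16.4 ± 0.82 CPM against 0 counts, at least 528-fold higher against the floor of 3 counts over the group's libraries. Xist, the transcript of the inactive X chromosome (X, 103460366 to 103483254), was at 349 ± 28.3 against 0.0311 CPM, the latter from 3 counts. The class II pseudogene H2-Ea-ps (chromosome 17, 34341959 to 34344645), polymorphic between strains, was at 187 ± 36.9 against 0.0108 CPM from 1 count. In all, 2639 genes were higher and 2888 lower of 14085 tested, 5527 in total. The total was 2944 with all 23 libraries in the fit (1150 higher and 1794 lower) and 6233 without HPV-negative macrophage library 4. In that library transcripts of its line stood at a median of 5.51%. Those of both MEER lines, a set not chosen as low in MEER macrophages, stood at 12.6%. Several of the largest changes were in genes with near-identical copies elsewhere, whose reads the counting could split, and these values are uncertain: Rpl3 stood at 1.38 against 1104 ± 30.8 CPM, Rps3a1 at 6.67 against 1027 and its copy Rps3a3 at 402 against 1.38, and Eno1b at 788 ± 11 against 0.114 CPM.

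The third pairing of macrophages set SCCVII against HPV-positive MEER, again with the mouse strain, and by Xist perhaps the sex of the hosts, changing along with the model. Nos2 changed by -6.95 ± 0.11 (edgeR quasi-likelihood adjusted p = 3.5e-10), Cd274 by -4.87 ± 0.15 (adjusted p = 1.1e-08) and Vegfa by -4.92 ± 0.09, from 820 to 28 CPM. Ccl24 was at 0.53 against 1675 CPM (log2 -11.66 ± 0.29) and Plet1, an epithelial surface protein, at 0.079 against 465 CPM (log2 -12.49 ± 0.36). The carbonic anhydrase Car4 (chromosome 11, 84957786 to 84966044) had 0 counts in SCCVII macrophages and was at least 513-fold lower. Higher in SCCVII macrophages were Cx3cr1 (log2 2.43 ± 0.22), the monocyte receptor Ccr2 (log2 1.82 ± 0.09) and Ctsk, at 42.4 against 3.3 CPM. Mrc1 did not pass the test (log2 -0.06 ± 0.21, adjusted p = 0.83).

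All 21 classical inflammatory genes fell (21 adjusted over the list alone, camera adjusted p = 2.6e-26, adjusted p = 0.12 with an estimated correlation), as did all 17 alternative activation genes (17 adjusted over the list alone, camera adjusted p = 6.7e-17, adjusted p = 0.052 with an estimated correlation) and all 12 MHC class II genes (12 adjusted over the list alone, camera adjusted p = 1.3e-06, adjusted p = 0.32 with an estimated correlation). Of 22 hypoxia genes 20 fell and 1 rose (20 and 1 adjusted over the list alone, camera adjusted p = 1.8e-10, adjusted p = 0.21 with an estimated correlation). Of 24 cytokine genes 17 fell and 4 rose (17 and 4 adjusted over the list alone, camera adjusted p = 1.8e-08, and adjusted p = 0.021 with an estimated correlation). All 22 mitotic genes rose (22 adjusted over the list alone, camera adjusted p = 4.2e-18, adjusted p = 0.2 with an estimated correlation). The mitotic activator Cdc20 stood at 65.6 against 14 CPM. Xist was at 349 CPM against 0 counts, at least 8170-fold higher. In all, 4542 genes were higher and 4359 lower of 14085 tested.

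The HPV-positive and HPV-negative MEER lines were compared in culture to give the tumour cells' own expression without a host. Mdm2, which encodes the ligase that degrades p53 (chromosome 10, 117688875 to 117710758), was far lower in the HPV-positive line, at 189 ± 25 against 3374 ± 650 CPM (log2 -4.17 ± 0.17, edgeR quasi-likelihood adjusted p = 8.5e-08). Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases, was at 168 ± 42.2 against 363 ± 90.2 CPM (log2 -1.12 ± 0.2), and Cdkn2a, the locus of p16 and p19 (chromosome 4, 89274471 to 89294653), at 180 ± 42.3 against 69.2 ± 21.4 CPM (log2 1.37 ± 0.25, adjusted p = 0.0013). The phosphatase gene Ptpn13 was at 10.3 against 34.7 CPM (log2 -1.77 ± 0.27). The macrophage growth factor Csf1 (chromosome 3, 107741048 to 107760469) was at 111 ± 33.9 against 508 ± 117 CPM (log2 -2.21 ± 0.23) and the chemokine Cxcl12 (chromosome 6, 117168535 to 117181367) at 0.368 ± 0.0731 against 416 ± 126 CPM (log2 -10.13 ± 0.29). Cd274 was low in both lines, at 0.769 against 5.42 CPM (log2 -2.82 ± 0.2). Trp53 itself changed by -0.29 ± 0.09 (adjusted p = 0.025), and that call was lost without HPV-negative line library 2 (-0.21) or HPV-positive line library 2 (-0.28).

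Of 26 p53 target genes 22 fell and none rose (22 adjusted over the list alone, camera adjusted p = 1.7e-10, adjusted p = 0.32 with an estimated correlation), among them the stress cytokine Gdf15, which changed by -4.79 ± 0.29. Of 28 E2F genes 25 rose and 1 fell (25 and 1 adjusted over the list alone, camera adjusted p = 4.8e-09, adjusted p = 0.48 with an estimated correlation). The replication factor Gins2 stood at 57.9 against 20.1 CPM. Of 22 mitotic genes 20 rose (21 adjusted over the list alone, camera adjusted p = 1.4e-07, adjusted p = 0.48 with an estimated correlation). Of 26 epithelial and keratinocyte genes 20 rose and 3 fell (20 and 3 adjusted over the list alone, camera adjusted p = 1.4e-07, adjusted p = 0.32 with an estimated correlation). The desmosomal cadherin Dsg2 was at least 370-fold higher, at 10.5 ± 1.42 CPM against 0 counts, while Trp63, the transcription factor of basal epithelium, changed by -5.76. Krt14, a basal keratin (chromosome 11, 100203162 to 100207548), did not pass the test (log2 -0.49 ± 0.84, adjusted p = 0.66), and passed at -2.27 without HPV-positive line library 1. Of 16 extracellular matrix genes 11 fell and 1 rose (12 and 1 adjusted over the list alone, camera adjusted p = 5.9e-06, adjusted p = 0.39 with an estimated correlation). The collagen cross-linker Lox stood at 0.841 against 41.8 CPM. Of 15 MHC class I genes 11 fell (11 adjusted over the list alone, camera adjusted p = 0.0049, adjusted p = 0.32 with an estimated correlation). The peptide transporter Tap1 stood at 2.69 against 15.9 CPM. Of 26 ribosomal protein genes 18 fell (21 adjusted over the list alone, camera adjusted p = 0.00072, adjusted p = 0.57 with an estimated correlation). In all, 3338 genes were higher and 3435 lower of 14396 tested, 6773 in total, against 4514 with the replicate block (2240 higher and 2274 lower). The largest changes included Stag3, a meiotic cohesin, at 175 ± 23.7 against 0.037 CPM, and Thbs2, a matrix protein, at 0.551 against 500 ± 120 CPM.

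The SCCVII line was compared with the HPV-negative MEER line as the tumour-cell counterpart of the macrophage comparison. Cdkn2a had 1 count over the SCCVII libraries, 0.0119 CPM against 69.2 ± 21.4 in the HPV-negative line. Mdm2 was lower, at 415 ± 3.99 against 3374 CPM (log2 -3.12 ± 0.16, edgeR quasi-likelihood adjusted p = 1.5e-07), and Cdkn1a did not pass the test (log2 -0.18, adjusted p = 0.46). Perp, a desmosomal p53 target (chromosome 10, 18845020 to 18857073), and the desmoplakin gene Dsp had 0 counts in SCCVII, Perp being at least 8090-fold lower from 249 ± 32.6 CPM and Dsp at least 329-fold lower. Col1a2, the fibrillar collagen chain (chromosome 6, 4504814 to 4541544), was at 1387 ± 40.3 against 2.01 CPM (log2 9.34 ± 0.19), and the retinoic acid binding protein gene Crabp1 (chromosome 9, 54764748 to 54773110) at 298 ± 11.1 against 0.0577 CPM (log2 12.17 ± 0.46). Pianp (chromosome 6, 124996694 to 125003096) was at least 3010-fold higher, at 85.6 ± 2.48 CPM against 0 counts. It was also high in SCCVII macrophages and low in MEER macrophages, so it may follow the strain. Csf1 was at 809 ± 16.9 against 508 CPM (log2 0.57 ± 0.22, adjusted p = 0.048), a call lost when any 1 library other than HPV-negative line library 1 was left out (0.42 to 0.63). Cd274 stood at 10.2 ± 0.911 against 5.42 CPM (log2 0.81 ± 0.18, adjusted p = 0.0026).

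Of 22 Ras and ERK output genes 19 fell and 2 rose (19 and 2 adjusted over the list alone), and the shift held with an estimated correlation (camera adjusted p = 6.2e-08 preset and adjusted p = 0.018 estimated). The growth factor gene Areg, an ERK-induced ligand of the EGF receptor, was at 3.34 against 111 CPM, while the feedback inhibitor Spry4 rose by 1.61 ± 0.11. Of 15 MHC class I genes 14 rose (14 adjusted over the list alone, camera adjusted p = 7.5e-05, adjusted p = 0.14 with an estimated correlation). The immunoproteasome subunit Psmb8 stood at 52.3 against 0.533 CPM. Of 16 matrix genes 9 rose and 5 fell (9 and 6 adjusted over the list alone, camera adjusted p = 0.00027, adjusted p = 0.86 with an estimated correlation). Of 22 mitotic genes 19 rose (20 adjusted over the list alone, camera adjusted p = 0.0019, adjusted p = 0.86 with an estimated correlation). Of 26 p53 targets 15 fell and 2 rose (16 and 2 adjusted over the list alone, camera adjusted p = 0.039, adjusted p = 0.86 with an estimated correlation). Of 26 epithelial genes 14 fell and 4 rose (14 and 4 adjusted over the list alone, camera adjusted p = 0.048, adjusted p = 0.86 with an estimated correlation), and without single libraries the p of this list rose as far as 0.067. In all, 3919 genes were higher and 4551 lower of 14396 tested.

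Between the SCCVII and HPV-positive lines, 4312 genes were higher and 4905 lower of 14396 tested. Csf1 was higher in SCCVII, at 809 against 111 CPM (log2 2.78 ± 0.24, edgeR quasi-likelihood adjusted p = 3.5e-06), as were Cxcl12, at 170 against 0.368 CPM, Cd274, at 10.2 against 0.769 CPM, and the monocyte chemokine Ccl2 (log2 3.7 ± 0.46). Mdm2 was at 415 against 189 CPM (log2 1.05 ± 0.15) and Cdkn2a at 0.0119, from 1 count, against 180 CPM. Of 15 MHC class I genes 14 rose (14 adjusted over the list alone, camera adjusted p = 2.7e-08, adjusted p = 0.073 with an estimated correlation). Of 28 E2F genes 25 fell (25 adjusted over the list alone, camera adjusted p = 2.7e-08, adjusted p = 0.54 with an estimated correlation). The replicative helicase subunit Mcm2 stood at 94.8 against 458 CPM. Of 26 epithelial genes 23 fell (23 adjusted over the list alone, camera adjusted p = 2.1e-07, adjusted p = 0.43 with an estimated correlation), and Perp was at least 5300-fold lower. Of 16 matrix genes 11 rose and 3 fell (11 and 3 adjusted over the list alone, camera adjusted p = 2.7e-08, adjusted p = 0.4 with an estimated correlation). Of 22 Ras and ERK output genes 18 fell and 2 rose (19 and 2 adjusted over the list alone, camera adjusted p = 3.8e-08, and adjusted p = 0.021 with an estimated correlation).

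**Figure D2:**
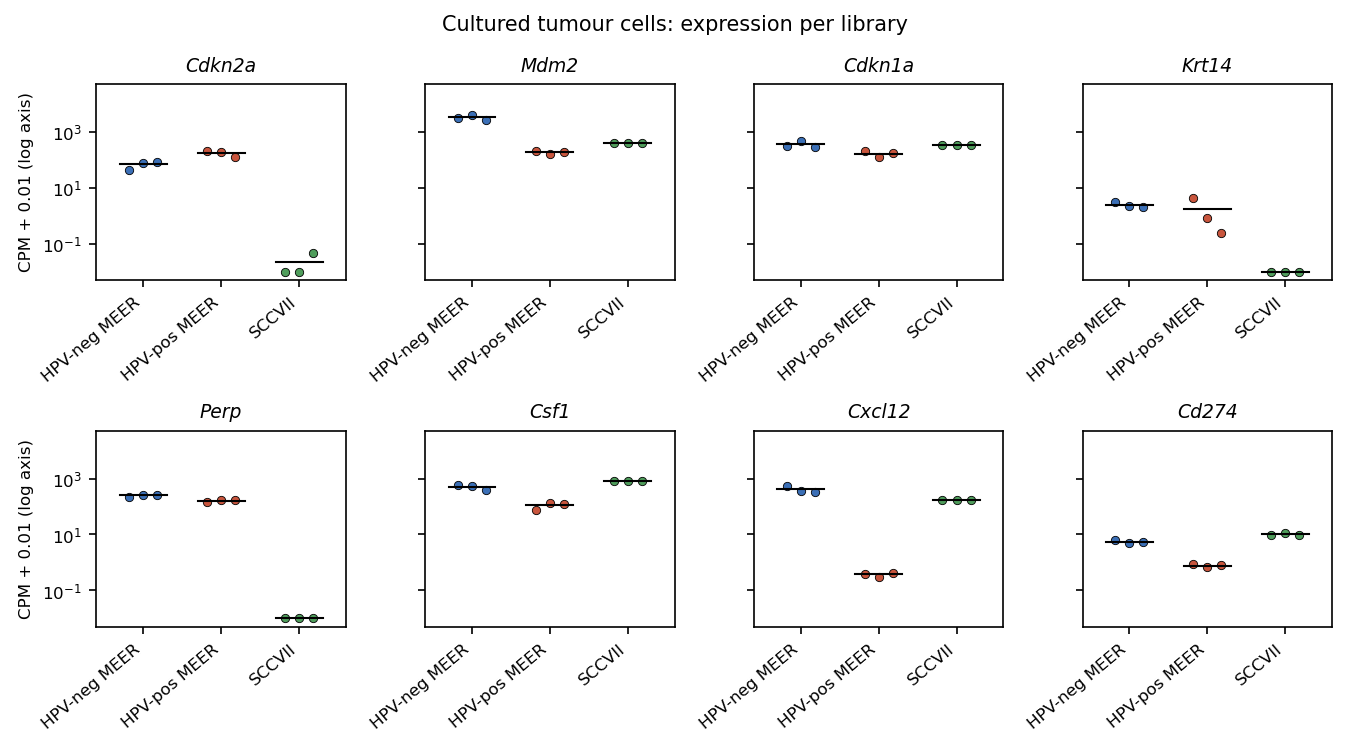
Expression of 8 genes in the cultured HPV-negative MEER, HPV-positive MEER and SCCVII tumour cells, as CPM + 0.01 on a log axis, where each point is a library and each black line the group mean. Mdm2 averaged 3374, 189 and 415 CPM in the 3 lines in that order, and Cdkn2a averaged 69.2, 180 and 0.0119 CPM.

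Macrophages were compared with the tumour cells of their own model to give the transcripts of each compartment of a tumour. All 17 macrophage identity genes were higher in macrophages in each of the 3 models, and this held with an estimated correlation (camera adjusted p = 2.7e-36, 6.7e-30 and 1e-32 preset and adjusted p = 0.011, 0.0048 and 0.006 estimated, for HPV-negative MEER, HPV-positive MEER and SCCVII, with 17 called in each when adjusted over the list alone). Adgre1, which encodes the F4/80 antigen used in the sort, was higher by 13.64 ± 0.38, 12.29 ± 0.36 and 11.44 ± 0.32 on the log2 scale. The platelet factor gene Pf4 was at 524 ± 56.3 CPM in HPV-negative macrophages against 0 counts in the line, at least 18400-fold higher, and Nos2 was at least 14700-fold higher in HPV-positive macrophages than in their line. Cd274 was higher in macrophages by 4.22 ± 0.14, 9.94 ± 0.19 and 1.37 ± 0.13 (edgeR quasi-likelihood adjusted p = 1.7e-13, 2e-16 and 6e-08). Csf1 was lower in macrophages than in the HPV-negative MEER and SCCVII lines (log2 -3.88 ± 0.36 and -7.12 ± 0.43) and higher than in the HPV-positive line (log2 1.58 ± 0.33, adjusted p = 0.00035). Cd34, a marker of progenitor and endothelial cells, was at 3.34 CPM in SCCVII macrophages against 970 CPM in their line.

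Of 19 checkpoint genes in HPV-positive MEER 18 were called higher in macrophages and 1 lower (the same counts adjusted over the list alone, camera adjusted p = 1.6e-09, and adjusted p = 0.009 with an estimated correlation). All 22 mitotic and 27 of 28 E2F genes were lower in HPV-positive macrophages than in their line (22 and 27 adjusted over the list alone, camera adjusted p = 1.3e-05 and 4.5e-07, adjusted p = 0.34 and 0.28 with an estimated correlation). In HPV-negative MEER 12 mitotic genes were higher and 4 lower (the same adjusted over the list alone, camera adjusted p = 0.51). The difference between the models was not tested for these lists. All 12 MHC class II genes were higher in macrophages in each model (12 adjusted over the list alone, camera adjusted p = 1.5e-07, 6e-09 and 4.9e-06, adjusted p = 0.12, 0.098 and 0.17 with an estimated correlation). In all, 6131 genes were higher and 5924 lower in HPV-negative MEER, 6278 and 6198 in HPV-positive MEER, and 5929 and 5628 in SCCVII, of 15835 tested.

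Colonies that the labels describe as derived from sorted macrophages were compared with the macrophage libraries of their model, though no label ties a colony to a macrophage pool. In SCCVII colonies 1 and 2, transcripts marking the SCCVII line stood at medians of 69.8% and 89.5% of their level in that line, and Col1a2, Col3a1, Col5a2 and Bgn of the matrix list are among them, so tumour cells may carry part of the changes below. In SCCVII, with 2 colony libraries, 10 of 12 MHC class II genes were lower and 17 of 18 matrix genes higher in the colonies (camera adjusted p = 0.00012 and 7.4e-07, adjusted p = 0.66 for each with an estimated correlation). C1qa, a chain of complement C1q made by macrophages, was at 0.305 against 3060 CPM (log2 -13.31 ± 3.89, edgeR quasi-likelihood adjusted p = 0.018), a call lost without either colony library (-14.01 and -12.8). H2-Eb1, a class II chain, was at 0.689 against 213 CPM (log2 -8.28 ± 1.22, adjusted p = 0.00055), and Arg1 at 24.2 against 680 CPM (log2 -4.81 ± 0.65, adjusted p = 0.00034). Cd34 rose by 8.28 ± 0.25, to 1042 ± 99.4 from 3.34 CPM, and stood at 970 CPM in the SCCVII line. The adhesion gene Cdh13 was at 342 ± 5.62 against 0.0453 CPM and the hypoxia-induced carbonic anhydrase Car9 at 618 against 8.63 CPM. Spread between the colony libraries was wide, with Adgre1 at 140 and 5.19 CPM in colonies 1 and 2 and Ptprc, the CD45 gene, at 113 and 3.78 CPM. Neither passed the test (log2 -3.78 ± 2.79, adjusted p = 0.28, and -3.55 ± 2.14, adjusted p = 0.19). Nos2 was called higher (log2 3.21 ± 0.91, adjusted p = 0.016), and its change was 0.05 and not called without colony 1.

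All 22 mitotic genes fell in SCCVII colonies (22 adjusted over the list alone, camera adjusted p = 7.6e-11, adjusted p = 0.66 with an estimated correlation), and Mki67 changed by -4.08 ± 0.84. Of 28 interferon-stimulated genes 24 fell (25 adjusted over the list alone, camera adjusted p = 1.9e-08, adjusted p = 0.66 with an estimated correlation). The chemokine Cxcl10 stood at 0.678 against 101 CPM. Of 12 MHC class II genes 10 fell (11 adjusted over the list alone, camera adjusted p = 0.00012, adjusted p = 0.66 with an estimated correlation). Of 18 matrix genes 17 rose and 1 fell (17 and 1 adjusted over the list alone, camera adjusted p = 7.4e-07, adjusted p = 0.66 with an estimated correlation). Of the haematopoietic progenitor genes 6 rose and 3 fell (edgeR calls, camera adjusted p = 0.18). In all, 4817 genes were higher and 3614 lower of 16238 tested, 8431 in total, against 5301 with the replicate block (2915 higher and 2386 lower). The prolactin-family genes Prl2c2 and Prl2c3, near-identical copies whose values are uncertain, were at 1850 ± 998 and 493 ± 396 CPM in colonies, against 0.0342 CPM from 3 counts and 0 counts in macrophages.

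In HPV-negative MEER the colony libraries also differed among themselves. Adgre1 was at 1239, 2.84 and 0.0302 CPM in colonies 1, 2 and 3, and its change did not pass the test (log2 -0.94 ± 2.12, edgeR quasi-likelihood adjusted p = 0.71), whereas without colony 1 it was -9.14 and called. Without colony 1, Ptprc likewise went from -3.54 ± 1.81 (adjusted p = 0.11) to -8.6 and was called, as were Csf1r at -10 and the integrin gene Itgam at -8.94. The class II chain H2-Aa was at 0.873 ± 1.19 against 2241 ± 1150 CPM (log2 -11.24 ± 1.47, adjusted p = 0.00032), Arg1 at 39.6 against 1629 CPM (log2 -5.36 ± 0.56) and Apoe changed by -8.79 ± 1.03. Higher in colonies were the secreted phosphoprotein gene Spp1, at 11277 ± 3958 against 1797 CPM (log2 2.62 ± 0.34), Cxcl12, at 584 against 2.52 CPM, and Trp63, at 36.5 ± 17.4 against 0.0406 CPM (log2 9.62 ± 0.78). Cxcl12 is among the transcripts marking the HPV-negative line, which stood in colonies 1, 2 and 3 at medians of 49.2%, 83% and 90.7%. Tumour cells may thus carry part of the changes here and in the lists below. The protease gene Prss35 was at 62.1 ± 17.9 CPM against 0 counts, at least 2000-fold higher.

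All 12 MHC class II genes fell in these colonies (12 adjusted over the list alone, camera adjusted p = 2.7e-06, adjusted p = 0.43 with an estimated correlation), as did 13 of 17 alternative activation genes (13 adjusted over the list alone, camera adjusted p = 7.6e-06, adjusted p = 0.43 with an estimated correlation) and 19 of 22 mitotic genes (21 adjusted over the list alone, camera adjusted p = 2.4e-05, adjusted p = 0.46 with an estimated correlation). T cell genes fell too, 13 of 14 (13 adjusted over the list alone, camera adjusted p = 1.7e-06, adjusted p = 0.43 with an estimated correlation), with Cd3g, a chain of the T cell receptor complex, at least 294-fold lower. Of 23 epithelial genes 17 rose and 1 fell (17 and 1 adjusted over the list alone, camera adjusted p = 6e-04, adjusted p = 0.43 with an estimated correlation), and of 18 matrix genes 14 rose and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 0.0023, adjusted p = 0.43 with an estimated correlation). Of 22 Ras and ERK output genes 14 rose and 3 fell (14 and 3 adjusted over the list alone, camera adjusted p = 0.0017, adjusted p = 0.46 with an estimated correlation). Of the haematopoietic progenitor genes 7 rose and 2 fell (camera adjusted p = 0.47). In all, 5513 genes were higher and 4665 lower of 16238 tested, 10178 in total, against 3315 with the replicate block (2470 higher and 845 lower). Beside these groups, transcripts of the HPV-negative line stood in colonies 1, 2 and 3 at medians of 49.2%, 83% and 90.7% of their level in that line, and Mdm2, chosen after its values were seen, was at 1338, 2449 and 1987 CPM. Library-wide expression of HPV-negative colony 1 correlated across genes at 0.856 with the macrophage mean and at 0.852 with the line mean, and that of colony 3 at 0.71 and 0.915, where genes are not independent replicates.

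**Figure D3:**
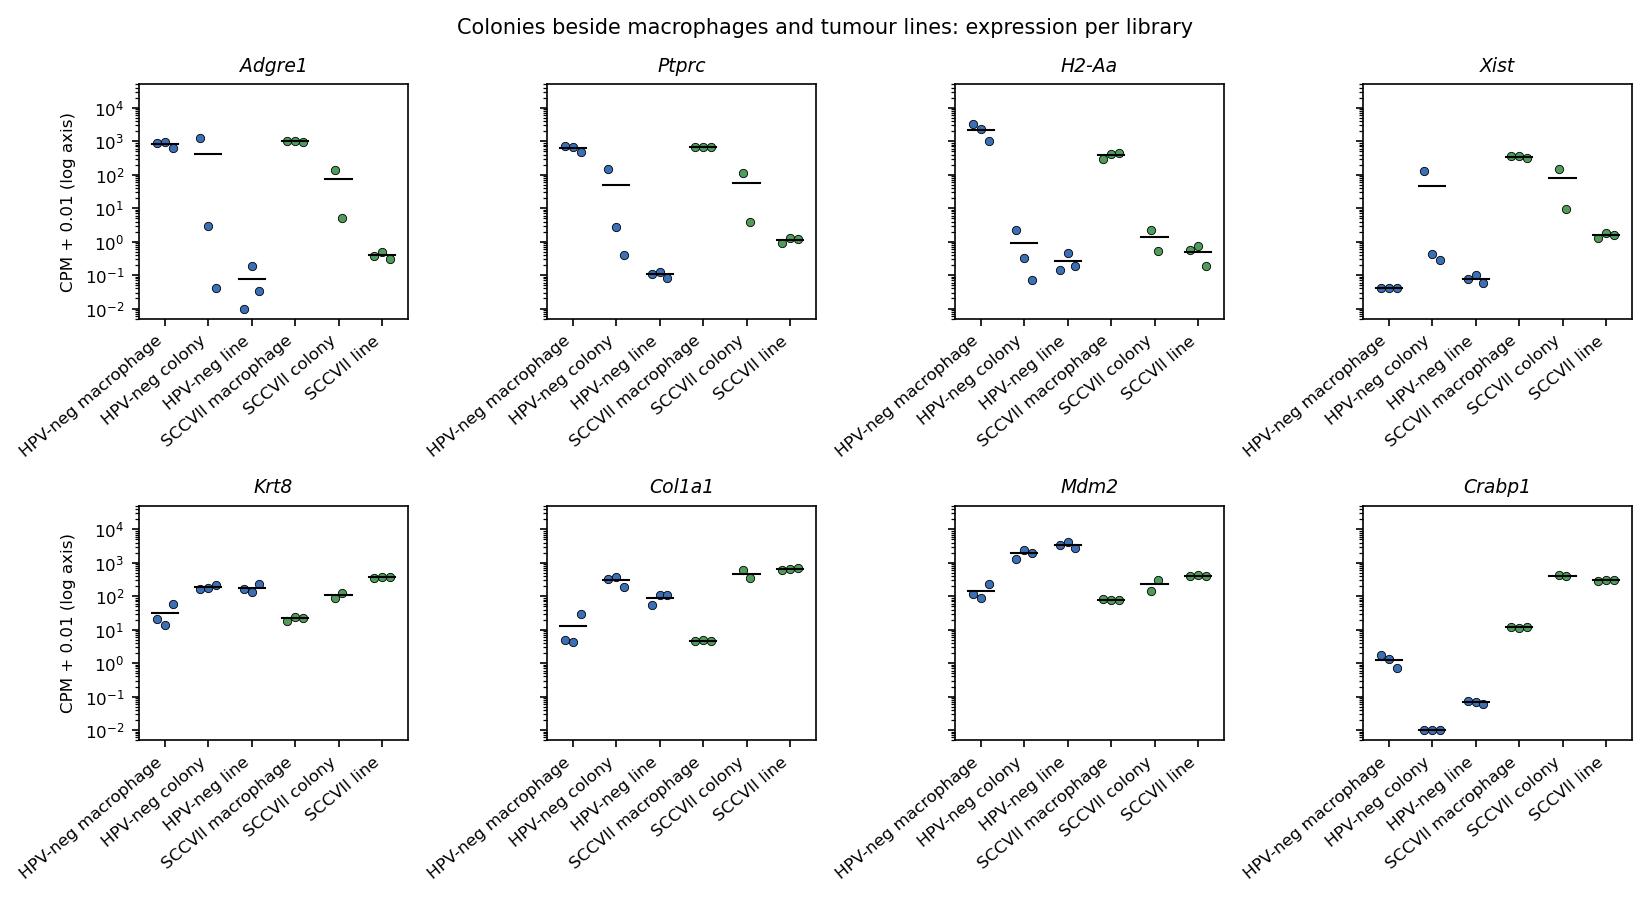
Expression of 8 genes in macrophages, colonies and tumour lines of HPV-negative MEER and SCCVII, as CPM + 0.01 on a log axis, where each point is a library and each black line the group mean. Adgre1 spans 0.0302 to 1239 CPM among the 3 HPV-negative colonies, and Crabp1 is at 439 and 392 CPM in the 2 SCCVII colonies and at 0 in the HPV-negative ones.

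Colonies of both models were compared directly, and the difference between the models in the change from macrophage to colony was tested as an interaction. Crabp1 was at 415 ± 32.9 CPM in SCCVII colonies against 0 counts, at least 16900-fold higher, and the proteoglycan gene Fmod was at least 4270-fold lower from 217 ± 137 CPM. Crabp1 and Cd34 are among the transcripts marking the SCCVII line and Fmod among those marking the HPV-negative line, and since own-line transcripts stood at 49.2% to 90.7% in the colonies, these differences and those of the lists may be those of the tumour lines. Cd34 was higher in SCCVII colonies (log2 5.82 ± 0.22, edgeR quasi-likelihood adjusted p = 1.9e-06), and the collagen chaperone gene Serpinh1 was at 685 ± 75.2 against 0.143 CPM (log2 12.04 ± 0.67). Of 28 interferon-stimulated genes 15 fell (19 adjusted over the list alone, camera adjusted p = 0.0018, adjusted p = 0.99 with an estimated correlation). The antiviral gene Oas2 stood at 0.63 against 48.8 CPM. Of 22 hypoxia genes 12 rose and 1 fell (14 and 2 adjusted over the list alone, camera adjusted p = 0.0029, adjusted p = 0.99 with an estimated correlation), and of 23 epithelial genes 11 fell and 1 rose (11 and 1 adjusted over the list alone, camera adjusted p = 0.0018, adjusted p = 0.99 with an estimated correlation). Between the colonies 3325 genes were higher in SCCVII and 3229 lower of 16238 tested, 6554 in total, against 3252 with the 2 groups alone (1646 higher and 1606 lower) and 1124 with the replicate block (529 higher and 595 lower). In the interaction 2192 genes were called higher and 1729 lower, with the interferon-stimulated list at 11 lower of 28 (13 adjusted over the list alone, camera adjusted p = 7.6e-06, adjusted p = 0.62 with an estimated correlation) and the ribosomal protein list at 17 higher and 1 lower of 26 (19 and 1 adjusted over the list alone, camera adjusted p = 4.9e-05, adjusted p = 0.56 with an estimated correlation). The interaction's total of 3921 calls moved with single libraries, being 2535 without SCCVII macrophage library 2 and 6949 without HPV-negative colony 1, and was 5904 with DESeq2 (3066 higher and 2838 lower) and 13 with the replicate block (11 and 2).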

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

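The tests on tumour-line transcripts in colonies, on Xist in HPV-negative colony 1 and on the share of pseudogenes were chosen only after the result was seen. So was the comparison of the HPV-positive minus HPV-negative change between macrophages and tumour cells.

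Transcripts of tumour lines stood high in every colony library. Transcripts marking the model's own line stood at medians between 49.2% of the line's level (HPV-negative colony 1) and 90.7% (colony 3). Those marking another line reached a median of at most 2.44% (SCCVII transcripts in HPV-negative colony 2). For most of these transcripts this argues against a culture programme of macrophage-derived cells without tumour cells. Some stood higher, with upper quartiles of 18.4% and 24.8% for the 36 HPV-negative line transcripts in SCCVII colonies 1 and 2. For the 54 SCCVII line transcripts it was 12.7% in HPV-negative colony 2. The sets of single MEER lines were chosen without regard to SCCVII samples, so the SCCVII line may express some of their genes. In SCCVII colony 2, Xist was at 2.71% of the macrophage mean. Host cells that had only lost their macrophage transcripts would keep Xist if their hosts carried it like the macrophage pools. No label ties this colony to a pool, so the Xist level cannot decide this. The values that tumour cells among the colony cells would need are there, with Crabp1 at 439 and 392 CPM in SCCVII colonies and Mdm2 at 1338 to 2449 CPM in HPV-negative colonies, so tumour cells carried through a gate that requires CD45 may be a source of these colonies. Whether they stood beside host cells or had fused with them was not tested, and an origin from macrophages stays open for the part of each model's colony 1 that carried Adgre1.

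Xist was at 134 CPM in HPV-negative colony 1, against at most 0.41 CPM in colonies 2 and 3 and 0.0324 CPM in HPV-negative macrophages. RNA of SCCVII samples in that library would bring transcripts marking the C3H strain, and these stood at a median of 0.541% of the SCCVII macrophage level, against 38.4% for Xist, which argues against it. Female hosts for part of the HPV-negative pools could give the 38.4%, but no Y-linked gene is among the matched genes, so this cannot be told apart from another origin of the library's host cells.

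Of 12729 genes tested in both cell types, 106 rose and 176 fell at least 8-fold in macrophages and in cultured cells of SCCVII against HPV-negative MEER, where independent lists would share 5.55 and 17.21. Sharing beyond independence was also there between HPV-positive and HPV-negative MEER, which are of the same strain, with 15 rising against 1.41 and 38 falling against 2.92. Own-line transcripts stood at medians of 0.557% to 5.51% in HPV-negative and 1.38% to 1.58% in HPV-positive macrophages. In SCCVII macrophages these were 0.828% to 0.984%. Crabp1, Shank3, Pet2 and Lhfpl4, which mark the SCCVII line, are among the 106 genes. Line RNA in macrophage libraries may thus add to the sharing, which was not tested. Separate changes in the transcription of each gene would not favour pseudogenes, yet these were 65.1% of the 106 genes, against 4.67% of the genes tested and 0 of the 15, which argues against that explanation. Reads of C3H alleles assigned to another copy could give the pattern, and 39.6% of the rising genes with sequence shared it with a gene lower in both, against a highest value of 20.8% among 100 random sets. That share lay under the 50% set beforehand as needed for this cause, so the test left it open. The rising genes without such a partner include many pseudogenes too, and what raised them was not settled.

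The change from macrophage to colony differed between SCCVII and HPV-negative MEER for 3921 genes by the edgeR quasi-likelihood test of the interaction (2535 without SCCVII macrophage library 2, 6949 without HPV-negative colony 1 and 13 with the replicate block). The block also left out libraries without a same-numbered partner, so the 13 cannot be laid to blocking alone. Among the largest differences were 13.47 ± 0.65 for Crabp1 (adjusted p = 1e-04) and 13.41 ± 0.89 for Tshz3 (adjusted p = 0.00031) on the log2 scale, both transcripts that mark the SCCVII line, so they may reflect tumour cells in the colonies. Those in the other direction were -14.63 ± 1.6 for Elobl (adjusted p = 0.0016), -12.51 ± 3.87 for Xist (adjusted p = 0.045) and -12.4 ± 0.56 for Nid2 (adjusted p = 4.6e-05). The Xist difference was -5.43 and not called without HPV-negative colony 1. Each of these genes is at or near 0 counts in at least 1 group, so the fitted sizes depend on the prior count.

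The HPV-positive minus HPV-negative change differed between macrophages and tumour cells for 6497 of 15835 genes, 3076 higher in macrophages and 3421 lower, and 1594 genes were called in both in opposite directions. With 48.7% of tested genes called in macrophages and 47% in lines, unrelated changes would also give many opposite calls. The 1594 therefore do not show a link between the cell types. Cd274 differed by 5.73 ± 0.21 (edgeR adjusted p = 2.3e-11), Csf1 by 5.46 ± 0.49 (adjusted p = 3.4e-07), Mdm2 by 3.73 ± 0.37 and Mki67 by -2.25 ± 0.38.

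Comparisons of 3 libraries with 3 make 10 splits, too few for a share under 0.05, and in each of 10 comparisons 1 of the 10 splits, the real one, reached the real count. The real counts were 6853, 5527 and 8901 for the macrophage comparisons, 6773, 8470 and 9217 for the lines, 10178 for HPV-negative colonies against macrophages, and 12055, 12476 and 11557 for macrophages against lines. The highest count of another split was 1 for HPV-negative colonies and for HPV-positive macrophages against their line, and 0 for the others, in edgeR.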

How the results depend on the processing

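Leaving out HPV-negative colonies 2 and 3 and leaving out pseudogenes were chosen after seeing the data. Over the alternatives run no list reversed, and 1589 results of named genes were refitted where a setting applied. Of these, 4 lost their call and 2 gained it with RLE size factors, 7 and 8 with DESeq2, 15 and 2 without a filter, 66 and 6 with the compared groups alone, 149 and 11 with all 23 libraries, 137 and 6 with the replicate block, and 54 and 9 with HPV-negative colony 1 alone. Over all left-out libraries 8835 refitted values stayed as they were, called or not called, while 430 lost a call, 24 gained one and 5 changed sign. With all 23 libraries in the fit, macrophages called 3708 genes between HPV-positive and HPV-negative MEER (6853 in 9 libraries) and 2944 between SCCVII and HPV-negative MEER (5527), and macrophages against lines shifted by medians of -0.121, -0.165 and -0.136 on the log2 scale. With the 2 groups alone, colonies of SCCVII and HPV-negative MEER differed in 3252 genes (6554). DESeq2 called 5904 genes in the interaction (3921). With the replicate number as a replicate block, counts were 4514 for HPV-positive against HPV-negative lines (6773), 5301 for SCCVII colonies against macrophages (8431), 3315 for HPV-negative ones (10178), 1124 between colonies and 13 in the interaction. Same-numbered samples deviated together at correlations of -0.11 to 0.33, not all over 0.1, so the numbers were not found to pair samples. With so few libraries per group a pairing cannot be excluded. With colonies the block also dropped libraries without a same-numbered partner, so those falls cannot be laid to blocking alone. Leaving out 1 library moved the interaction between 2535 and 6949 genes and no other count by more than 1.5 times. It changed the sign of 5 results, each without the colony library numbered 1 of a model, and none was called in both directions. S100a8 in HPV-negative colonies against macrophages (-1.02 to 4.77, 4.14 with all) and, between colonies, Igf1 (-0.16 to 3.05) and Vwf (-0.04 to 6.85) were called with all libraries and not called at the reversed value (adjusted p = 0.093, 0.85 and 0.97). Adgre1 (-6.37 to 5.6) and Csf1r (-4.27 to 4.05) between colonies were not called with all libraries (adjusted p = 0.45 and 0.46) and were called higher in SCCVII without HPV-negative colony 1 (adjusted p = 0.021 and 0.015). With HPV-negative colony 1 as the lone colony, assumed to vary like the other groups, 7200 genes were called against macrophages, 5328 against SCCVII colonies and 3905 in the interaction. Without pseudogenes, SCCVII against HPV-negative and HPV-positive MEER gave 5330 and 8611 genes in macrophages and 8201 and 8908 in lines, and 6242 between colonies. An estimated correlation ended 166 list calls among 453 list results. The 287 list results that stayed as they were had mostly not been called with the preset correlation, so most calls were lost. Apart from smaller sets of libraries, the cause of these shifts was not tested. Depth sets the floor at 0.063 to 0.112 CPM.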

Other observations

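The genes around Mdm2 and Cdkn2a were chosen after the values of these 2 genes had been seen, though the tests on them were written before their own values were read.

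Further lists held called genes in macrophages of HPV-positive against HPV-negative MEER tumours, though the osteoclast list did not shift as a whole. Of 19 immediate early and heat shock genes 15 rose and none fell (15 adjusted over the list alone, camera adjusted p = 7.7e-09, adjusted p = 0.2 with an estimated correlation), with the stress-induced transcription factor Atf3 at 836 against 81.4 CPM (log2 3.39 ± 0.26). Cdh1, which encodes E-cadherin, was at 443 against 53.9 CPM (log2 3.06 ± 0.22). Of 10 osteoclast genes 2 rose and 6 fell (the same adjusted over the list alone, camera adjusted p = 0.95). The 2 that rose, Ocstamp (log2 3.34 ± 0.16) and Dcstamp (3.21), are fusion proteins of osteoclasts and giant cells, while Atp6v0d2, a proton pump subunit, changed by -1.88. Of 24 myeloid-acting cytokine genes 14 rose and 5 fell (14 and 5 adjusted over the list alone, camera adjusted p = 0.001, adjusted p = 0.12 with an estimated correlation).

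Hypoxia genes stood higher in the SCCVII line than in both MEER lines, with 12 of 22 higher and 1 lower against HPV-negative MEER (12 and 1 adjusted over the list alone, camera adjusted p = 0.034, adjusted p = 0.86 with an estimated correlation) and 15 higher and 1 lower against HPV-positive MEER (15 and 1 adjusted over the list alone, camera adjusted p = 0.0067, adjusted p = 0.63 with an estimated correlation). Car9 changed by 3.71 and 6.53 on the log2 scale. In SCCVII colonies against macrophages, 17 of 27 cytokine genes rose and 4 fell (17 and 4 adjusted over the list alone, camera adjusted p = 0.0042, adjusted p = 0.66 with an estimated correlation). The neutrophil chemokine Cxcl5 was at 110 and 5.52 CPM in colonies 1 and 2 (58 ± 74.2) against 0 counts, so the bound of 1720-fold on the mean rests on colony 1, and the alarmin Il33 rose by 10.21 ± 1.17. Of 25 lysosome and lipid handling genes 15 were higher in SCCVII than in HPV-negative colonies and 1 lower (15 and 1 adjusted over the list alone, camera adjusted p = 0.0018, adjusted p = 0.99 with an estimated correlation), a call lost without SCCVII colony 1 (adjusted p = 0.055). Ctsk was at 3118 CPM in SCCVII colony 1 and 109 CPM in colony 2.

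A hypothesis for the 1 count of Cdkn2a in the SCCVII line is a loss of its chromosomal region, which would take neighbouring genes along. Mtap (chromosome 4, 89137122 to 89181081) was at 0.1 CPM in that line, against 185 CPM in the HPV-negative and 222 CPM in the HPV-positive line, the value such a loss may give. Klhl9 was at 0.0623 CPM against 96.8 and 83.3, and Cdkn2b at 0.0214 CPM against 16.6 and 76.1, whereas Focad was at 18.7 CPM against 33.3 and 22.3. These genes at or under 0.1 CPM lie between 88718292 and 89311039 on GRCm38. Further out, Zfp352 (90218820 to 90225702) was at 0 CPM in SCCVII, but it was low in the other lines too, at 1.91 and 0.164 CPM. The end of the stretch is thus not fixed on that side. SCCVII colonies 1 and 2 had Mtap at 10.2 and 0.93 CPM. No DNA was measured, so a loss of expression without a loss of DNA stays open.

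A hypothesis for the high Mdm2 of the HPV-negative line is a gain of its chromosomal region, which would lift its neighbours. The 11 other genes within 1 Mb had a median log2 change of -0.57 between the HPV-positive and HPV-negative lines, between the bounds of -1 and -0.5 set beforehand, so the test left this open. Cpm changed by -4.21, Yeats4 by -1.75 and Mdm1 by -1.35, while Rab3ip changed by 0.97 (6 genes called lower and 1 higher). Between SCCVII and HPV-negative lines Cpm changed by -2.21, Yeats4 by -2.06 and Mdm1 by -1.3, while Rab3ip changed by 1.12. The median of the 11 genes was 0.09 there, where a gain of the whole window in the HPV-negative line would give a fall.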
